A study of Mus musculus with 9 samples.

How the data were processed

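RNA was sequenced from the media (the smooth muscle layer) of mouse femoral arteries. The 9 libraries form 3 groups of 3: sham-operated arteries, arteries collected 14 days after wire injury, and arteries collected 14 days after wire injury from mice given the focal adhesion kinase (FAK) inhibitor VS-4718. Per the labels, the inhibitor was given by mouth at 50 mg/kg, in 2 doses per day for 2 weeks, and citrate buffer was the vehicle otherwise. Per the labels, fat and adventitia were dissected away and the lumen was rinsed with a lysis reagent to take off endothelial and immune cells before RNA was isolated. The groups are called sham, injured and inhibitor-treated below, and a library is named by its group and replicate number. The labels number the replicates but do not say how many animals stand behind a library, so p-values measure only the spread between these samples, which may be technical.

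The authors deposited 3 tables, one per pair of groups, each with 6 libraries. Per the file headers, each table gives normalised read counts per gene for each library, a log2 fold change, a p-value and an adjusted p-value, and a gene name. The values in the library columns are a normalised signal that the authors made by dividing each library's counts by one factor per library, set separately in each table; this was read from the values themselves. The value of 1 read was estimated in each deposited column from its low values. Dividing by it returned whole reads for 100% of values in every library, within 0.01 of a read, and a library present in 2 tables gave the same reads in both for every gene shared. The aligner, the counting program, its use of strand and the authors' test are not given in the sources used here. Per the submitters' processing notes, the genome build was mm10, also called GRCm38. The deposited log2 fold changes and p-values of the authors were used only as an alternative and where named as theirs. The tables hold 16315 genes (injured and sham), 16933 (inhibitor-treated and injured) and 16187 (inhibitor-treated and sham), and 15592 genes are in all 3. Low genes are absent: the smallest mean normalised count over the libraries of a table was 9.22, 9.63 and 9.46. Gene names that a spreadsheet had turned into dates, 21 per table, were replaced through the gene identifier, and 14 to 16 genes per table had no name.

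The recovered reads came to between 14672571 and 21247261 per library. Levels set across all 3 groups were rescaled from these reads with one median-of-ratios factor per library over the 9 libraries and the 16750 genes present in at least 2 tables, because the 3 tables were scaled separately. The tests used each comparison's own table, apart from 1 alternative that fitted all 9 rescaled libraries. Replicates were compared before averaging: the Pearson correlation of log2 values lay between 0.953 and 0.987, and the chi-square per degree of freedom between 11.7 and 102, so no pair of libraries was a repeat of another within sampling noise.

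Each comparison was tested within its own table with limma 3.58.1 in R 4.3.3, on log2(normalised count + 1), with a trended variance, group as the only term and a two-sided moderated test. Genes with a mean normalised count under 10 over the 6 libraries were left out, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are therefore on the log2(value + 1) scale, which understates the change of low genes. Errors beside log2 fold changes are standard errors, and errors beside levels are standard deviations over 3 libraries. An exact permutation test of 3 against 3 libraries cannot give a two-sided p under 0.1, so no such test was used for single genes. The design had named edgeR for whole counts and limma for normalised values, and limma was used because the deposited values are normalised.

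Before the data were examined, 30 gene lists were fixed: lists of smooth muscle state, matrix, cell cycle, inflammation, adhesion, chromatin, signalling and metabolism, and markers of other cell types that an artery sample can hold. Each list was tested against all other genes with camera at a preset correlation between genes of 0.01, with adjustment over the 30 lists of a comparison. It was tested again with a correlation estimated from the data. That fit also takes its degrees of freedom from the 6 libraries of a comparison, so it has little power to pass a list. Each list was also tested with fry, which asks whether the members differ from no change and not from other genes. Fry is left out of the ranges given beside camera. A list is tested on the members present in that comparison's table, from which genes low in both groups are absent. For each list, members past the threshold were counted among all genes tested and adjusted over the list alone. The lists are hand-made and share some members. A further 11 lists (such as hepatocyte, globin and circadian clock genes) were written after the data were examined and were only described, not tested for enrichment.

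The genes named in the text follow a rule fixed before the data were examined. It takes 11 genes whatever their result (Ptk2, Acta2, Myh11, Tagln, Cnn1, Myocd, Dnmt3a, Ccnd1, Mki67, Spp1 and Col1a1). It adds, per comparison, the 8 largest rises and the 8 largest falls among called genes with a symbol, a mean of at least 100 and no overlap between the groups' values, and from each list the 4 members with the smallest p-value. Predicted genes without a proper symbol were passed over among the largest changes. Some genes that the rule or a small count would name are not reported here. Members named to complete a count of 5 or fewer, and per-library examples from lists written later, were chosen after their values were seen. Of 49 genes named by the first 2 parts of the rule, 7 share over 10% of their exon bases with another annotated gene (Rmrp, Rpph1, Tagln, Ccnd1, Spp1, Gal3st3 and Alas2). Reads of the shared bases cannot be told apart from their neighbours' without strand. For Rmrp, Rpph1 and Spp1 a neighbour lies on the same strand, so strand would not separate all of their reads. Hspa1a and Hspa1b, the alpha globins, the beta globins and the immunoglobulin genes have near-identical copies among which the counting could split reads, so their values are uncertain.

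Comparisons that share libraries share their chance values. The reversal of injury changes was therefore set beside 100 simulated draws in which the third group was drawn with no inhibitor effect, and beside draws in which it was drawn as sham. The number of genes that 2 independent lists would share was given as well. Splitting 3 shared libraries leaves under 2 on a side, so no split was made.

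The alternatives were a replicate block, leaving out each library in turn, no filter on low values or a mean of at least 100, quantile normalisation, DESeq2 1.42.0 on the recovered reads, the authors' adjusted p, pseudocounts of 0.1 and 10, sample weights, 1 fit of all 9 libraries, an absolute log2 fold change of at least 1, and an adjusted p under 0.01. Others were added after seeing the data: the quasi-likelihood test of edgeR 4.0.16 on the recovered reads, fits without 3 of the libraries that stood apart (injured replicate 2, sham replicate 3 and inhibitor-treated replicate 3), counts without blood, liver, skeletal muscle, small RNA, histone and immunoglobulin genes, and the medians of all lists under other scalings. The edgeR test called 6033, 6108 and 997 genes in the 3 comparisons.

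The calling of genes was tested on simulated data, with counts drawn for the real genes and 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold. For injured against sham (15211 genes), limma called 6% of the genes changed 1.5-fold, 35.8% of those changed 2-fold and 86.4% of those changed 4-fold. For inhibitor-treated against injured (16233 genes) the shares were 4.5%, 31.3% and 77.3%, and for inhibitor-treated against sham (15326 genes) 31.3%, 74.6% and 87.9%. In the simulated data limma called 94, 81 and 140 genes in all, against 6076, 6099 and 983 in the real comparisons. Of the simulated calls, 9, 6 and 11 were false, in genes that had not been changed. In each comparison this was a larger share of the calls than the threshold set for the adjusted p-value. With fewer changed genes the adjustment asks for a smaller p-value, so the shares of changed genes called may be lower than those in the data. How far the shares of changed genes called and of false calls apply to the data was not tested. Within that limit, a change of these sizes in a gene that did not pass the threshold is not excluded.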

Results

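RNA from the media of C57BL/6 mouse femoral arteries was measured as normalised read counts per gene in 9 libraries, 3 from sham-operated arteries, 3 from wire-injured arteries at day 14, and 3 from wire-injured arteries at day 14 of mice given a focal adhesion kinase (FAK) inhibitor. Between 14672571 and 21247261 reads were recovered per library. The study's title concerns FAK activity and transcription while smooth muscle cells switch phenotype, and the 3 pairwise comparisons address which transcripts differ with injury, with the inhibitor in injured arteries, and between inhibitor-treated and sham arteries. On the 1000 most variable genes, the leading component held 46.7% of the variance and the next 33.4%. The 3 groups were separate on these 2 components.

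**Figure D1:**
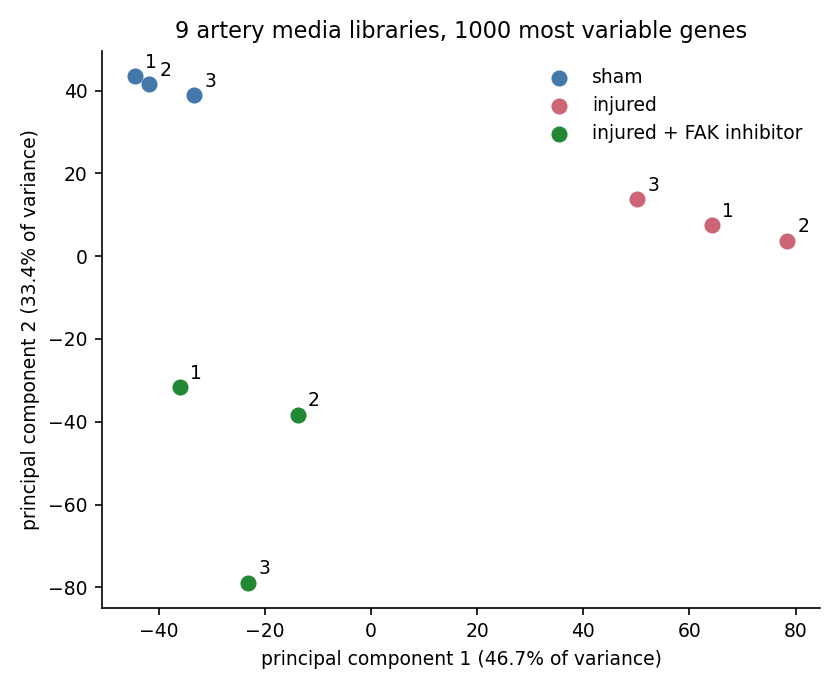
Principal components of the 9 libraries on the 1000 genes with the highest variance of log2 normalised counts, with 1 point per library coloured by group. The horizontal axis holds 46.7% and the vertical axis 33.4% of the variance, and inhibitor-treated replicate 3 lies at -78.8 on the vertical axis, against -31.6 and -38.3 for the others of its group.

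Some libraries stood apart within their group, on lists of marker genes measured as the mean log2 normalised count. The skeletal muscle list lay at 13.1 in injured replicate 2, against 10.5 and 9.48 in the other injured libraries, at 9.76 in sham replicate 3 against 7.82 and 7.67, and at 9.77 in inhibitor-treated replicate 2 against 6.92 and 8.18. The hepatocyte list lay at 10.1 in inhibitor-treated replicate 3 and between 1.60 and 2.71 in the 8 others. Erythroid genes other than globins lay between 7.93 and 9.37 in the inhibitor-treated libraries and between 2.26 and 2.82 in the 6 others. Rn7sk, the 7SK small nuclear RNA that carries no poly(A) tail, lay between 16224 and 26973 in the inhibitor-treated libraries and between 4.36 and 28.1 in the 6 others. Xist, the RNA of the inactive X, and the Y-linked Ddx3y were both present in every library, at 2654 to 11014 and 849 to 1814. The sex of the animals was not used here.

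The injured arteries were compared with the sham arteries to find the transcripts that differ 14 days after wire injury. Of the contractile smooth muscle genes 24 of 30 fell, while 24 of 27 inflammatory, 27 of 30 cell cycle and 13 of 20 collagen genes rose. These 4 lists passed with a preset correlation and not with an estimated one (adjusted p = 0.303 to 0.678 with an estimated correlation), and the list of other matrix genes passed with neither. Acta2, smooth muscle alpha actin (ENSMUSG00000035783, GRCm38 chromosome 19, 34241090 to 34255590), fell from 246260 ± 41734 to 66369 ± 4266 normalised counts (SD, n = 3 per group), a log2 fold change of -1.88 ± 0.29 (SE, limma adjusted p = 0.00126). Myh11, smooth muscle myosin heavy chain (ENSMUSG00000018830, chromosome 16, 14194535 to 14291372), fell by 1.93 ± 0.27 on the log2 scale (adjusted p = 0.000778). Spp1, the matrix protein osteopontin (chromosome 5, 104435118 to 104441050), rose from 92.2 ± 7.39 to 5514 ± 2071, by 5.81 ± 0.28 (adjusted p = 1.07e-05).

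Among the other genes fixed for naming, Tagln (SM22 alpha) fell by 1.49 ± 0.17, Cnn1 (calponin) fell by 2.11 ± 0.16, and Myocd, the coactivator that drives contractile genes, fell from 1117 ± 68.1 to 283 ± 119. Mki67, a marker of dividing cells (chromosome 7, 135689784 to 135716361), rose from 68.8 ± 8.30 to 672 ± 90.7, by 3.27 ± 0.17 (adjusted p = 1.33e-05). Ccnd1, a G1 cyclin, rose by 0.92 ± 0.13, and Col1a1, a chain of type I collagen, rose by 2.02 ± 0.26. Ptk2, the gene of FAK itself (ENSMUSG00000022607, chromosome 15, 73205102 to 73423280), was at 1007 ± 27.6 in sham and 1228 ± 105 in injured arteries, a log2 fold change of 0.28 ± 0.11 that did not pass the test (adjusted p = 0.0684). It passed in 3 alternatives, with quantile normalisation, with sample weights and with all 9 libraries in 1 fit. Dnmt3a, a de novo DNA methyltransferase, was at 1584 ± 170 and 1467 ± 80.4 (adjusted p = 0.505).

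**Figure D2:**
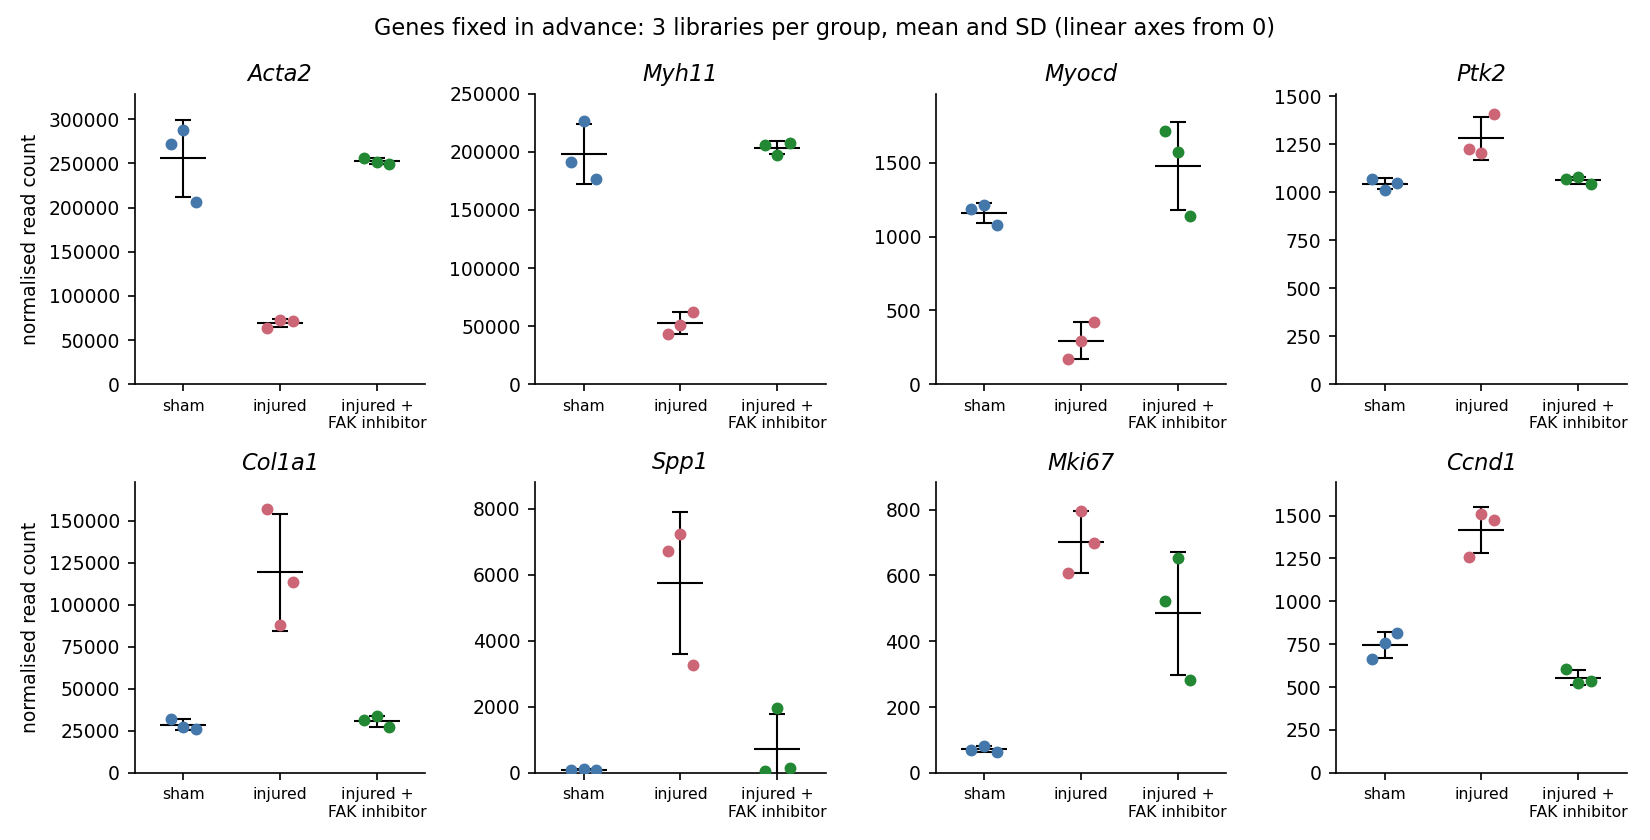
Normalised counts of 8 named genes in each library, on 1 scale for all 9 libraries and a linear axis from 0, with the mean and SD of each group (n = 3; the lower SD bar of Spp1 with the inhibitor runs below 0 and is not drawn there). Acta2, Myh11 and Myocd are lowest in injured arteries, and Mki67 is above the sham level in both injured groups.

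Among called genes with a symbol, a mean of at least 100 and no overlap between the groups, from which the largest changes are named in each comparison, the 8 largest rises were in Saa3 (an acute-phase protein), Mmp12 (macrophage elastase), Col10a1 (type X collagen of hypertrophic cartilage), Fbn2 (a fibrillin), Il1rn (the interleukin-1 receptor antagonist), Ms4a4c (a membrane protein of immune cells), Il1b (interleukin-1 beta) and Ngp (a neutrophil granule protein). Their log2 fold changes ran from 6.42 ± 0.91 for Ngp to 8.86 ± 0.75 for Saa3, which went from 1.99 ± 1.93 to 1465 ± 1010. The largest falls included Dsp (desmoplakin of desmosomes), Sost (the Wnt inhibitor sclerostin), Tceal6 (of an elongation factor family), Lgr6 (an R-spondin receptor), Olfr224 (an olfactory receptor), Gal3st3 (a sulfotransferase) and Ucp1 (the uncoupling protein of brown fat). Dsp fell from 3523 ± 220 to 5.69 ± 4.29 (log2 fold change -9.26 ± 0.43), and Sost fell from 10236 ± 3736 to 40.4 ± 32.5 (-8.15 ± 0.48). Ucp1 was uneven among sham arteries, at 2287 ± 2462.

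The limma test covered 16278 genes and called 6076, of which 3346 rose and 2730 fell. In 8348 genes the values of the 2 groups did not overlap, where chance gives 10% of genes. The authors' deposited table gave 6425 genes at an adjusted p under 0.05, with 3578 higher and 2847 lower. Without the genes of blood, liver, skeletal muscle, small RNA, histone and immunoglobulin lists 5984 genes were called, and 4128 without injured replicate 2 and sham replicate 3. Those 2 and inhibitor-treated replicate 3 were left out of this alternative wherever they occur, while inhibitor-treated replicate 2, also higher on the skeletal muscle list, was kept.

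The 30 gene lists were tested with camera, and 17 passed, 13 upward and 4 downward. With a correlation estimated from the data 0 lists passed and 4 were under 0.05 unadjusted. This fit gave the highest adjusted p over 9 camera alternatives for each of the 17. For matrix proteases and inhibitors the estimated correlation was -0.005, below the preset one, yet the unadjusted camera p went from 6.49e-06 to 0.00697. Not passing this fit is therefore not by itself a sign of correlated members. With fry, which tests a list against no change and not against other genes, 16 lists passed, and its values are outside the ranges given. The NuRD list passed with fry and not with camera (fry adjusted p = 0.00882). The oxidative phosphorylation (0.368) and skeletal muscle (0.16) lists passed with camera and not with fry. Where a count was 5 or fewer, members outside the fixed rule were named after their values were seen.

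Of the 30 contractile smooth muscle genes, 24 fell and 1, Casq2 (a calcium store protein), rose, with the same counts adjusted over the list alone. The list median was -1.51 (camera adjusted p = 1.33e-11, adjusted p = 0.365 with an estimated correlation, range over the alternatives 1.29e-13 to 0.365). Itga8, an integrin of contractile muscle, fell from 48411 ± 3696 to 4412 ± 1299, Kcnmb1, a potassium channel subunit, fell by 2.36 ± 0.13, and Lmod1, an actin filament nucleator, fell by 2.05 ± 0.14. Of 30 FAK, integrin and focal adhesion genes, 19 fell and 5 rose, or 20 and 7 adjusted over the list alone, with a median of -0.82 (adjusted p = 0.000154, adjusted p = 0.564 with an estimated correlation, range 8.03e-05 to 0.564). Lims2 (PINCH2) fell by 2.08 ± 0.11, Zyx (zyxin) fell by 1.95 ± 0.11 and Itga9 fell by 2.22 ± 0.17. The 5 that rose were Ptk2b (the FAK relative PYK2), Pxn (paxillin), Tln2 (talin 2), Itga4 and Itga11. Of 18 immediate early and heat shock genes, 10 fell and 2, Egr2 and Junb, rose, in both counts (median -0.63, adjusted p = 0.00776, adjusted p = 0.678 with an estimated correlation, range 0.000616 to 0.678). Hspa1a fell from 1948 ± 217 to 412 ± 47.2 and Dusp1 fell by 1.38 ± 0.11.

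Of 26 genes of modulated smooth muscle, 17 rose and 5 fell in both counts (median 1.05, adjusted p = 0.00713, adjusted p = 0.493 with an estimated correlation, range 0.00205 to 0.493). Lgals3 (galectin 3) rose by 3.46 ± 0.27 and Col8a1 by 2.47 ± 0.16, while Myh10 (non-muscle myosin IIB) fell by 2.70 ± 0.21 and Vim and Nes were among the others that fell. Of 20 collagens, 13 rose and 2, the basement membrane chains Col4a5 and Col18a1, fell, in both counts (median 1.02, adjusted p = 0.00238, adjusted p = 0.678 with an estimated correlation, range 7.93e-05 to 0.678). Col5a3 rose from 236 ± 18 to 2140 ± 304 and Col11a1 from 16.7 ± 0.284 to 1026 ± 847. Of 29 matrix proteases and inhibitors, 21 rose and 3, Mmp23 and Adamts1 among them, fell, in both counts (median 1.51, adjusted p = 2.43e-05, adjusted p = 0.209 with an estimated correlation, range 2.77e-06 to 0.209). Ctss (cathepsin S) rose by 4.88 ± 0.24, Ctsk (cathepsin K) by 2.11 ± 0.15 and Plau (urokinase) by 2.45 ± 0.13. Of 18 chondro-osteogenic genes, 10 rose and 3, Alpl, Cytl1 and Hapln1, fell, or 10 and 4 adjusted over the list alone (median 1.05, adjusted p = 0.0248, adjusted p = 0.365 with an estimated correlation, range 0.0131 to 0.365). Without injured replicate 3 this list was at an adjusted p of 0.0734. Runx1, Acan (aggrecan) and Col2a1 rose by 3.66 ± 0.25, 2.33 ± 0.15 and 6.08 ± 0.31.

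Of 30 cell cycle genes, 27 rose and 1, the replication factor Mcm6, fell, or 28 and 1 adjusted over the list alone (median 1.77, adjusted p = 8.38e-12, adjusted p = 0.303 with an estimated correlation, range 2.23e-12 to 0.303). Top2a rose from 73.3 ± 11 to 594 ± 65.1 and Cdk1 from 17.8 ± 4.64 to 211 ± 34.7. Of 27 inflammatory cytokine, chemokine and adhesion genes, 24 rose and 1, Ptgs2 (cyclooxygenase 2), fell, in both counts (median 3.25, adjusted p = 3.6e-09, adjusted p = 0.36 with an estimated correlation, range 5.7e-10 to 0.36). Ccl8 rose from 29.6 ± 6.11 to 1029 ± 410 and Cxcl16 by 2.36 ± 0.21. All 22 interferon response genes rose in both counts (median 2.15, adjusted p = 1.42e-08, adjusted p = 0.564 with an estimated correlation, range 1.15e-10 to 0.564), among them Oas2 by 3.87 ± 0.28 and Xaf1 by 1.79 ± 0.15.

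Markers of other cell types moved with injury beside these groups. All 24 macrophage and monocyte markers rose in both counts (median 3.49, adjusted p = 2.91e-16, adjusted p = 0.36 with an estimated correlation, range 4.95e-17 to 0.36). Ccr2 rose from 51.9 ± 6.02 to 2257 ± 494, Adgre1 (F4/80) by 3.65 ± 0.16 and Cd68 by 3.44 ± 0.16. All 11 neutrophil markers rose in both counts (median 5.02, adjusted p = 2.24e-06, adjusted p = 0.437 with an estimated correlation, range 2.61e-08 to 0.437), among them Csf3r by 4.36 ± 0.27 and S100a8 by 6.24 ± 0.64. Of 16 lymphocyte markers 14 rose, or 15 adjusted over the list alone (median 3.48, adjusted p = 3.83e-07, adjusted p = 0.437 with an estimated correlation, range 2.38e-08 to 0.437), Cd4 by 4.39 ± 0.32 and Igkc by 4.65 ± 0.31. Of 20 endothelial markers 13 rose in both counts (median 0.70, adjusted p = 0.000155, adjusted p = 0.578 with an estimated correlation, range 1.15e-05 to 0.578), among them Robo4 by 1.54 ± 0.17 and Kdr (VEGF receptor 2) by 1.67 ± 0.22. Of 16 Schwann and neuronal markers 9 rose, or 9 with 1 lower adjusted over the list alone (median 1.00, adjusted p = 0.00776, adjusted p = 0.578 with an estimated correlation, range 0.00254 to 0.578), among them Egr2 by 2.12 ± 0.19.

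Of 25 skeletal muscle markers 15 rose and 1, Tcap, fell, or 18 and 1 adjusted over the list alone (median 3.16, adjusted p = 0.0064, adjusted p = 0.751 with an estimated correlation, range 6.62e-07 to 0.751). Tnni1 rose by 4.33 ± 0.63, and Pvalb rose from 703 ± 528 to 18507 ± 22075, with Myh4 at 162620 in injured replicate 2 and 14160 and 10184 in the other injured libraries. The call for Tcap was lost in 4 of the 6 fits that left out 1 library. Of 30 nuclear genes of oxidative phosphorylation, Ndufv1, Cox8a and Cyc1 fell and none adjusted over the list alone (median -0.29, adjusted p = 0.0243, adjusted p = 0.8 with an estimated correlation, range 0.000446 to 0.8). The list's adjusted p was 0.195 without sham replicate 3 and 0.286 without injured replicate 3, and each of the 3 genes lost its call in at least 2 of 6 such fits.

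The other 13 lists did not pass. Counts of members higher and lower are given here with the list median and, last, the counts adjusted over the list alone. Other extracellular matrix genes gave 13 and 4 of 30 (0.25, then 13 and 5), with Lum (lumican) higher by 2.17 ± 0.18 and Thbs1 (thrombospondin 1) by 2.59 ± 0.27, and fibroblast markers gave 9 and 3 of 20 (0.36, then 9 and 3). DNA methylation genes gave 3 and 2 of 17 (0.04, then 3 and 2), where Uhrf1 and Gadd45a rose by 2.23 ± 0.29 and 1.59 ± 0.27 and Tet1 fell by 1.22 ± 0.24. NuRD complex genes gave 0 and 4 of 14 (-0.13, then 0 and 4), where Chd3 fell by 0.93 ± 0.12 and Rbbp4 by 0.52 ± 0.10. TGF-beta and BMP genes gave 3 and 7 of 24 (-0.14, then 3 and 8), with Grem1 up by 3.37 ± 0.36 and Ltbp1 lower (-1.63 ± 0.16), and growth factor and Notch genes gave 9 and 7 of 24 (0.26, then 11 and 8), with Igf1 up by 2.96 ± 0.19 and the Notch target Heyl lower (-1.37 ± 0.16). Glycolysis gave 0 and 5 of 17 (-0.14, then 0 and 5), with Pfkp lower (-1.23 ± 0.13), and its adjusted p was 0.00205 without injured replicate 2 (range over the alternatives 0.00205 to 0.779). Fatty acid and lipid genes gave 3 and 4 of 22 (-0.29, then 2 and 3), with the cholesterol exporter Abca1 up by 1.78 ± 0.24. Unfolded protein response genes gave 4 and 3 of 19 (0.10, then 5 and 3), adipocyte markers 3 and 3 of 15 (0.60, then 3 and 3), and erythroid and platelet markers 3 and 3 of 9 (-0.94, then 3 and 4). Mitochondrially encoded and nuclear-retained transcripts gave 1 and 3 of 14 (-0.69, then 1 and 1), with Meg3 up by 1.70 ± 0.24, and ribosomal proteins gave 0 and 0 of 28 (0.18), with 3 higher and 0 lower at an unadjusted limma p under 0.05. Besides glycolysis, lists that passed when 1 library was left out were other matrix genes (without sham replicate 1, 0.0459, or injured replicate 2, 0.0144, range 0.0144 to 0.809), fibroblast markers (without injured replicate 2, 0.0363, range to 0.751), mitochondrially encoded and nuclear-retained transcripts (without sham replicate 1, 0.00658, range to 0.751) and ribosomal proteins (without injured replicate 3, 0.000346, range to 0.871). Scaling on ribosomal protein genes put the median of all genes at -0.183 in this comparison, 0.325 in inhibitor-treated against injured and 0.163 in inhibitor-treated against sham, from -0.003, 0.006 and -0.007. Under it, the medians of the DNA methylation and unfolded protein lists changed sign, to -0.14 and -0.09, and under quantile normalisation that of glycolysis did, to 0.04.

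Inhibitor-treated injured arteries were compared with injured arteries to find the transcripts that differ with the inhibitor after injury. Of the contractile genes 26 of 30 rose, while 24 of 24 macrophage, 21 of 27 inflammatory, 19 of 22 interferon response and 13 of 20 collagen genes fell. These 5 lists passed with a preset correlation and not with an estimated one (adjusted p = 0.0879 to 0.646 with an estimated correlation). Acta2 rose from 71990 ± 4606 to 263310 ± 3453 (SD, n = 3 per group), by 1.87 ± 0.17 (limma adjusted p = 0.000271), Myh11 rose by 1.98 ± 0.19 (adjusted p = 0.000326), and Myocd rose from 307 ± 130 to 1540 ± 312. Beside these changes, erythroid, platelet and 7SK transcripts were higher in all 3 inhibitor-treated libraries, and hepatocyte transcripts were high in replicate 3 of them. Library preparation cannot be told apart from the treatment, so changes with the inhibitor are differences of the treated group and not a tested effect.

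Tagln and Cnn1 rose by 1.52 ± 0.10 and 2.03 ± 0.10. Col1a1 fell by 1.92 ± 0.23 and Ccnd1 fell by 1.34 ± 0.11. Mki67 was at 729 ± 96.3 in injured and 506 ± 196 in inhibitor-treated arteries, a log2 fold change of -0.60 ± 0.29 that did not pass (adjusted p = 0.148). It passed with sample weights (-0.65), and its log2 fold change was -0.25 without inhibitor-treated replicate 3 and ran from -0.86 to -0.16 over the alternatives. Ptk2 was at 1333 ± 121 and 1108 ± 19.9 (-0.26 ± 0.10, adjusted p = 0.0702), and Dnmt3a at 1592 ± 92.3 and 1880 ± 73.9 (0.24 ± 0.09, adjusted p = 0.0681). Of these, Ptk2 passed with quantile normalisation, with sample weights and with all 9 libraries in 1 fit, and Dnmt3a without injured replicate 3 and with sample weights. Spp1 fell from 5974 ± 2222 to 756 ± 1107 (-4.29 ± 1.11, adjusted p = 0.0213). Its call was lost without injured replicate 1 or 2 and without inhibitor-treated replicate 1 or 3, where the log2 fold change lay between -4.13 and -3.28. It was also lost with DESeq2, with edgeR, without injured replicate 2 and inhibitor-treated replicate 3 together and at an adjusted p under 0.01. Over all alternatives the log2 fold change lay between -5.70, without inhibitor-treated replicate 2, and -2.98, with edgeR, and the authors' deposited table gave it no adjusted p.

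Among called genes with a symbol, a mean of at least 100 and no overlap, the largest rises included Rn7sk, Slc4a1, Alas2 and Epb42 (genes of red cell precursors and membranes), Dsp, Rmrp (the RNA of RNase MRP) and Sost. Rn7sk rose by 10.34 ± 0.19, and Alas2, the erythroid enzyme of heme synthesis, rose from 110 ± 49.5 to 51124 ± 22469. Dsp rose from 6.18 ± 4.66 to 3445 ± 279 and Sost from 43.8 ± 35.2 to 12466 ± 1462. The 8 largest falls were in Col10a1, Col2a1, Ltf (lactoferrin of neutrophil granules), Fbn2, Igha (the IgA heavy chain), Ngp, Saa3 and Thbs4 (thrombospondin 4). Col10a1 fell from 1046 ± 629 to 11.8 ± 11.2 (-6.53 ± 0.68), and Thbs4 fell by 5.06 ± 0.94.

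The limma test covered 16901 genes and called 6099, of which 2976 rose and 3123 fell, and values did not overlap in 8720 genes against 10% by chance. The authors' deposited table gave 6768 genes, 3211 higher and 3557 lower. Without the blood, liver, skeletal muscle, small RNA, histone and immunoglobulin genes 5993 were called, and 3295 without injured replicate 2 and inhibitor-treated replicate 3. Of the 30 lists 18 passed, 5 upward and 13 downward. With an estimated correlation 0 passed and 3 were under 0.05 unadjusted, and with fry 19 passed. The NuRD (fry adjusted p = 0.0187), TGF-beta and BMP (0.00594) and chondro-osteogenic (0.011) lists passed with fry and not with camera. The skeletal muscle (0.196) and ribosomal protein (0.18) lists passed with camera and not with fry.

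Of 30 contractile genes, 26 rose and 1, Casq2, fell, in both counts (median 1.60, camera adjusted p = 1.54e-13, adjusted p = 0.0879 with an estimated correlation, range 5.37e-15 to 0.0879). Kcnmb1 rose by 2.30 ± 0.09, Mrvi1 by 2.08 ± 0.11 and Lmod1 by 2.00 ± 0.11. Of 30 FAK, integrin and focal adhesion genes, 19 rose and 4, Ptk2b, Pxn, Tln2 and Itga11, fell, or 22 and 5 adjusted over the list alone (median 1.12, adjusted p = 2.9e-06, adjusted p = 0.45 with an estimated correlation, range 2.47e-06 to 0.45). Lims2, Zyx, Itga3 and Itga7 rose by 1.89 ± 0.08, 2.10 ± 0.10, 1.49 ± 0.08 and 1.52 ± 0.08. Of 18 immediate early and heat shock genes, 10 rose and 1, Egr2, fell, in both counts (median 0.66, adjusted p = 0.00948, adjusted p = 0.646 with an estimated correlation, range 0.00093 to 0.646). Without injured replicate 3 this list was at 0.0535. Hspa1a and Hspb1 rose by 2.64 ± 0.26 and 1.67 ± 0.17.

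Of 26 modulated smooth muscle genes, 14 fell and 4 rose, or 16 and 5 adjusted over the list alone (median -0.76, adjusted p = 0.00562, adjusted p = 0.433 with an estimated correlation, range 0.0021 to 0.433). Lum and Dcn, small proteoglycans, fell by 2.37 ± 0.17 and 1.59 ± 0.16, and Myh10, Vim and Nes were among the 4 that rose, Myh10 by 2.65 ± 0.23. Of 20 collagens, 13 fell and 2, Col18a1 and Col4a5, rose, in both counts (median -1.15, adjusted p = 0.00381, adjusted p = 0.646 with an estimated correlation, range 0.000121 to 0.646). Col8a1 fell from 9624 ± 1630 to 2058 ± 293, and Col5a3 fell by 2.52 ± 0.23. Of 30 other matrix genes, 14 fell and 3, Emilin1, Ogn and Ctgf, rose, or 15 and 4 adjusted over the list alone (median -0.46, adjusted p = 0.014, adjusted p = 0.646 with an estimated correlation, range 0.000383 to 0.646). This list was at 0.0938 without injured replicate 3, and Ltbp2 and Comp fell by 1.82 ± 0.15 and 1.67 ± 0.14. Of 29 matrix proteases and inhibitors, 18 fell and 4, Mmp23, Timp4 and Adamts1 among them, rose, or 20 and 4 adjusted over the list alone (median -0.98, adjusted p = 0.000215, adjusted p = 0.349 with an estimated correlation, range 9.34e-05 to 0.349). Ctss fell from 6188 ± 2250 to 364 ± 111, and Plau and Mmp2 fell by 2.30 ± 0.13 and 2.26 ± 0.22.

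Of 30 cell cycle genes, 22 fell and 3, Ccne2, Bub1b and Mcm6, rose, in both counts (median -1.15, adjusted p = 2.66e-06, adjusted p = 0.433 with an estimated correlation, range 1.56e-07 to 0.433). Cdk1 and Ccnb1 fell by 2.72 ± 0.26 and 2.91 ± 0.35. Of 27 inflammatory genes 21 fell, or 25 with 1 higher adjusted over the list alone (median -2.25, adjusted p = 5.98e-08, adjusted p = 0.433 with an estimated correlation, range 5.42e-09 to 0.433), Ccl12 from 250 ± 92.8 to 12.2 ± 2.57 and the alarmin Il33 from 2291 ± 346 to 482 ± 60.8. Of 22 interferon response genes, 19 fell and 1, Rsad2 (viperin), rose, or 20 and 1 adjusted over the list alone (median -1.72, adjusted p = 3.24e-07, adjusted p = 0.486 with an estimated correlation, range 2.14e-08 to 0.486). Mx1 fell by 4.45 ± 0.43. Blood transcripts were high in the same 3 inhibitor-treated libraries, and hepatocyte transcripts in replicate 3 alone.

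All 24 macrophage and monocyte markers fell in both counts (median -3.15, adjusted p = 5.61e-14, adjusted p = 0.433 with an estimated correlation, range 2.56e-15 to 0.433). Ms4a7 fell by 5.03 ± 0.22, Csf1r from 3262 ± 445 to 445 ± 66.4 and Ccr2 by 3.99 ± 0.21. Of 20 endothelial markers 14 fell, or 15 adjusted over the list alone (median -0.74, adjusted p = 5.88e-06, adjusted p = 0.349 with an estimated correlation, range 2.15e-07 to 0.349), Emcn by 1.11 ± 0.08 and Kdr by 1.39 ± 0.11. Of 20 fibroblast and adventitial markers, 13 fell and 2, Pcolce2 and Pi16, rose, in both counts (median -0.69, adjusted p = 0.00103, adjusted p = 0.433 with an estimated correlation, range 9.34e-05 to 0.433). Penk fell by 3.43 ± 0.28 and Cd34 by 0.96 ± 0.09. Of 16 Schwann and neuronal markers 6 fell, or 7 adjusted over the list alone (median -0.73, adjusted p = 0.00293, adjusted p = 0.486 with an estimated correlation, range 0.000194 to 0.486), among them S100b by 0.92 ± 0.11. Of 25 skeletal muscle markers 5, Tnni1, Myh1, Myh2, Mb and Mybpc1, fell, or 20 with 1 higher adjusted over the list alone (median -3.34, adjusted p = 0.00293, adjusted p = 0.646 with an estimated correlation, range 1.17e-05 to 0.646). The skeletal muscle list lay highest in injured replicate 2 of the 6 libraries, and Myh1, Myh2 and Mybpc1 lost their calls in 2, 5 and 4 of the 6 fits that left out 1 library.

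Of 13 erythroid and platelet markers 11 rose in both counts (median 2.05, adjusted p = 7.89e-06, adjusted p = 0.454 with an estimated correlation, range 2.23e-07 to 0.454). Slc4a1 (band 3) rose by 8.86 ± 0.63 and Ppbp, a platelet chemokine, from 79.9 ± 32.0 to 12775 ± 6423. The 4 alpha and beta globins, a list written after the data were examined, had a median of 0.94, and 2 of them rose. Of 14 mitochondrially encoded and nuclear-retained transcripts 7 rose and 1, Meg3, fell, or 8 and 1 adjusted over the list alone (median 0.63, adjusted p = 0.014, adjusted p = 0.568 with an estimated correlation, range 0.00703 to 0.568). The adjusted p of this list was 0.0547 without injured replicate 3. Of 28 ribosomal protein genes 6 fell and none adjusted over the list alone (median -0.32, adjusted p = 0.00224, adjusted p = 0.646 with an estimated correlation, range 5.55e-07 to 0.646). Among them Rps18 fell by 0.62 ± 0.16 and lost its call in 4 of 6 fits that left out 1 library.

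**Figure D3:**
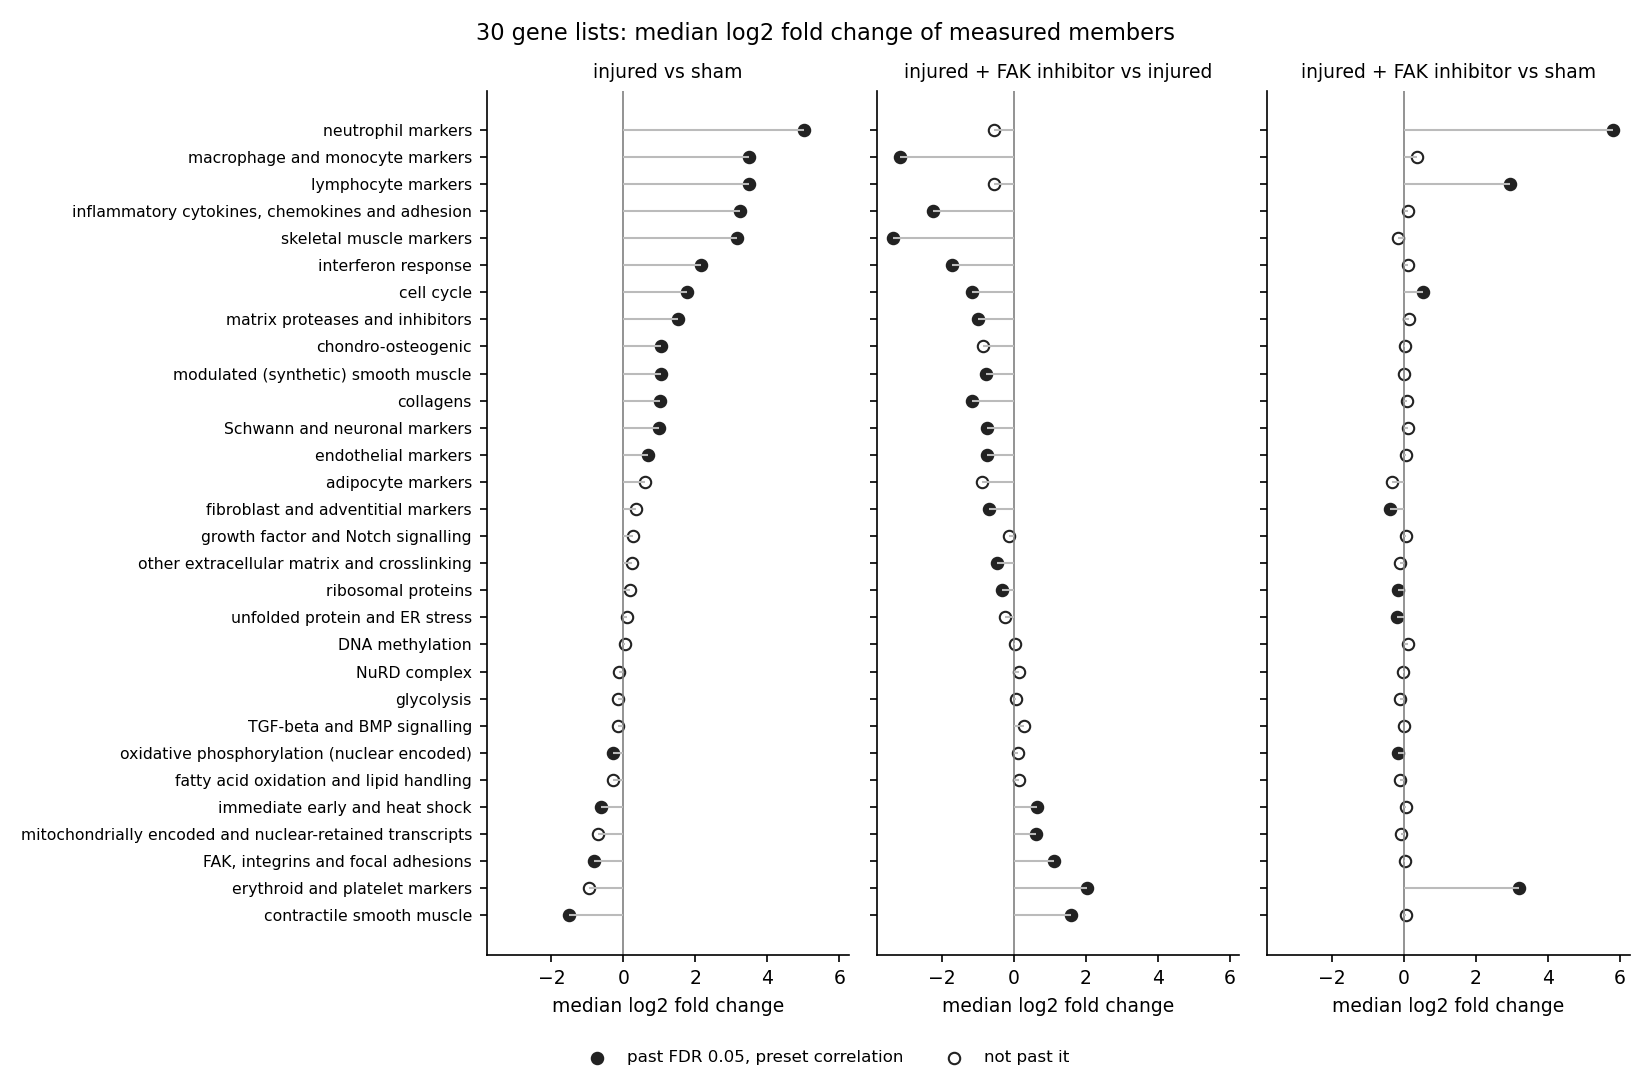
Median log2 fold change of each of the 30 gene lists in the 3 comparisons. A filled point passed a threshold of 0.05 with the preset correlation and an open point did not, and none passed with an estimated correlation.

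The other 12 lists did not pass in inhibitor-treated against injured arteries. Members higher and lower, with the median and then the counts adjusted over the list alone, were 1 and 1 of 17 for DNA methylation (0.05, then 1 and 1), with Uhrf1 lower (-1.67 ± 0.28), and 4 and 1 of 14 for NuRD (0.15, then 5 and 1), with Chd3 up by 0.68 ± 0.10 and Hdac2 the member that fell. TGF-beta and BMP genes gave 9 and 3 of 24 (0.28, then 11 and 5), with Ltbp1 up by 1.72 ± 0.11 and Bmper lower (-2.98 ± 0.25). Growth factor and Notch genes gave 8 and 7 of 24 (-0.13, then 8 and 9), with Hey2 up by 1.24 ± 0.10 and Igf1 lower (-2.95 ± 0.23). Chondro-osteogenic genes gave 3 and 9 of 18 (-0.84, then 3 and 9, adjusted p = 0.0572), with Runx2 lower (-2.22 ± 0.16). Oxidative phosphorylation gave 1 and 0 of 30 (0.13, then 0 and 0), glycolysis 5 and 1 of 17 (0.06, then 5 and 1), fatty acid and lipid genes 6 and 6 of 22 (0.15, then 7 and 6), and unfolded protein genes 1 and 7 of 19 (-0.25, then 1 and 7), with Pdia6 lower (-0.75 ± 0.08). Relative to ribosomal protein genes the medians of the Notch and unfolded protein lists were 0.19 and 0.07. Neutrophil markers gave 2 and 5 of 11 (-0.56, then 2 and 5), where Retnlg and Cxcr2 rose and the granule genes Mpo, Camp, Ltf, Ngp and Lcn2 fell. Lymphocyte markers gave 2 and 4 of 18 (-0.53, then 2 and 4), where the B cell gene Ms4a1 was among those that rose, and adipocyte markers 3 and 9 of 15 (-0.89, then 3 and 9), where Ucp1 rose from 26.8 ± 7.62 to 1470 ± 456 and Cfd fell by 1.90 ± 0.24. Lists that passed when 1 library was left out were oxidative phosphorylation (0.00212, range to 0.842), glycolysis (0.00298, range to 0.665) and adipocyte markers (0.00672, range to 0.646) without injured replicate 2, and unfolded protein genes without injured replicate 3 (0.0239, range to 0.646). Chondro-osteogenic genes passed without injured replicate 2 (0.0355), inhibitor-treated replicate 2 (0.0228) or replicate 3 (0.0116), with a range over the alternatives of 0.0112 to 0.486.

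Inhibitor-treated injured arteries were also compared with sham arteries. Of 30 contractile genes 0 were called, with 3 higher at an unadjusted limma p under 0.05. Among measured markers, 12 of 17 lymphocyte, 6 of 7 neutrophil, 9 of 13 erythroid and platelet and 6 of 30 cell cycle genes rose, 0 of 4 globins were called, and 8 of 20 fibroblast markers fell. These lists other than globins, which were not tested, passed with a preset correlation and not with an estimated one (adjusted p = 0.0818 to 0.779 with an estimated correlation), and with fry the fibroblast and cell cycle lists were at 0.056 and 0.0952. Acta2 was at 254290 ± 41321 in sham and 253540 ± 2876 in inhibitor-treated arteries (SD, n = 3 per group, log2 fold change 0.01 ± 0.17, limma adjusted p = 0.983). Mki67 rose from 71.1 ± 8 to 487 ± 187, by 2.68 ± 0.28 (adjusted p = 0.00118). Alas2 rose from 246 ± 86.6 to 49202 ± 21505, and Rn7sk rose by 10.34 ± 0.57.

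Log2 fold changes of the other fixed genes were 0.06 ± 0.15 for Myh11, 0.04 ± 0.12 for Tagln, -0.06 ± 0.12 for Cnn1, 0.15 ± 0.09 for Dnmt3a, 0.11 ± 0.12 for Col1a1 and 0.04 ± 0.06 for Ptk2, with no call. Myocd was at 1154 ± 62.0 and 1482 ± 296 (adjusted p = 0.215), and it passed without inhibitor-treated replicate 3, at 0.51. Ccnd1 was at 743 ± 80.4 and 556 ± 43.8 (-0.41 ± 0.10, adjusted p = 0.0564), and the authors' deposited table gave it an adjusted p of 0.0196. Spp1 was at 95.3 ± 7.02 and 726 ± 1063 (adjusted p = 0.442).

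Among called genes with a symbol, a mean of at least 100 and no overlap, the largest rises included Rn7sk, Rpph1 (the RNA of RNase P), Ppbp, Cd226 (a receptor of platelets and lymphocytes), Rmrp, Slamf1 (a lymphocyte receptor) and Ctse (cathepsin E). Rpph1 rose from 5.28 ± 2.58 to 3282 ± 440, and Slamf1 was listed at 0 in the 3 sham libraries and at 356 ± 230 with the inhibitor. The largest falls among such genes, under 1 on the log2 scale where 2 genes of a lower mean fell by more, included Myoz2 (a sarcomere protein), Vstm2b, Akr1c14, Pi16, Wisp2 (a matricellular protein), Lefty1 and Wnt5a. Wnt5a fell from 881 ± 29.1 to 517 ± 11.3 and Akr1c14 fell by 0.80 ± 0.13. The calls for Vstm2b and Lefty1 were lost in 5 of the 6 fits that left out 1 library, where they lay from -0.89 to -0.62 and -0.86 to -0.62.

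The limma test covered 16166 genes and called 983, of which 832 rose and 151 fell, and values did not overlap in 4506 genes against 10% by chance. The share that rose was 84.6%, against 73.7% with quantile normalisation and 95% with all 9 libraries in 1 fit. The authors' deposited table gave 1442 genes, 1152 higher and 290 lower. Without the blood, liver, skeletal muscle, small RNA, histone and immunoglobulin genes 862 were called, and 978 without sham replicate 3 and inhibitor-treated replicate 3. Transcripts of blood cells outside the hand-made lists are still among the 862. The count was 518 without sham replicate 1, 596 without sham replicate 2, 598 without inhibitor-treated replicate 1 and 533 without inhibitor-treated replicate 2. Of the 30 lists 8 passed, 4 upward and 4 downward. With an estimated correlation 0 passed and 2 were under 0.05 unadjusted, and with fry 3 passed. Besides the fibroblast and cell cycle lists, 3 more passed with camera and not with fry. These were oxidative phosphorylation (fry adjusted p = 0.741), unfolded protein (0.207) and ribosomal protein genes (0.0774). Without sham replicate 2 the number of lists was 15.

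Of 13 erythroid and platelet markers 9 rose, or 9 with 1 lower adjusted over the list alone (median 3.19, camera adjusted p = 7.94e-07, adjusted p = 0.77 with an estimated correlation, range 6.02e-08 to 0.77), Slc4a1 from 14.2 ± 5.44 to 2874 ± 1393 and Ppbp from 29.5 ± 15.9 to 12286 ± 6144. The 4 globins had a median of -0.36 and no call. Of 7 neutrophil markers 6 rose, or 7 adjusted over the list alone (median 5.82, adjusted p = 2.21e-09, adjusted p = 0.0818 with an estimated correlation, range 1.02e-09 to 0.0818), S100a8 by 6.98 ± 0.31 and Retnlg by 6.69 ± 0.36. This test holds only the 7 markers in that table. Over the 11 markers measured in the 9 libraries, which add granule genes that were low in both groups such as Ltf (3.96 ± 2.25 and 2.48 ± 1.42), the mean log2 level was 2.78 ± 0.361 in sham and 5.82 ± 0.242 in inhibitor-treated libraries. Of 17 lymphocyte markers 12 rose, or 15 adjusted over the list alone (median 2.94, adjusted p = 7.18e-10, adjusted p = 0.625 with an estimated correlation, range 8.55e-12 to 0.625), Cd3e by 3.35 ± 0.50 and Cd3g by 3.61 ± 0.56. Of 30 cell cycle genes 6 rose, or 10 with 1 lower adjusted over the list alone (median 0.54, adjusted p = 0.00096, adjusted p = 0.779 with an estimated correlation, range 9.33e-07 to 0.779). Bub1b, a mitotic checkpoint kinase, rose from 44.2 ± 18.4 to 510 ± 279.

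Of 20 fibroblast and adventitial markers 8 fell, or 15 adjusted over the list alone (median -0.39, adjusted p = 2.5e-07, adjusted p = 0.77 with an estimated correlation, range 6.42e-09 to 0.77), Ly6a by 0.53 ± 0.08, Serpinf1 by 0.41 ± 0.06 and Pi16 by 0.79 ± 0.13. Of 28 ribosomal protein genes 0 were called, with 17 lower at an unadjusted limma p under 0.05, or 8 fell adjusted over the list alone (median -0.17, adjusted p = 4.96e-07, adjusted p = 0.834 with an estimated correlation, range 3.68e-07 to 0.834). Both counts were 0 for 19 unfolded protein genes, with 8 lower at an unadjusted p (median -0.20, adjusted p = 0.00218, adjusted p = 0.834 with an estimated correlation, range 2.74e-05 to 0.834) and for 30 oxidative phosphorylation genes, with 3 lower. The latter had a median of -0.15 (adjusted p = 0.0134, adjusted p = 0.957 with an estimated correlation, range 2.95e-05 to 0.962), which was 0.02 relative to ribosomal protein genes. Its adjusted p was 0.962 without sham replicate 3 and 0.0816 without inhibitor-treated replicate 3.

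The other 22 lists did not pass in inhibitor-treated against sham arteries. Blood cell transcripts were high in all 3 inhibitor-treated libraries, and whether members called in these lists come from artery cells was not tested. Both counts were 0 for the following, given with the list median and the members higher and lower at an unadjusted limma p under 0.05: contractile genes (0.05, 3 and 0 of 30), collagens (0.08, 5 and 2 of 20), growth factor and Notch genes (0.06, 4 and 0 of 24) and endothelial markers (0.06, 1 and 0 of 20). The same held for adipocyte markers (-0.34, 0 and 2 of 15), and for Schwann and neuronal markers (0.12, or -0.08 with quantile normalisation, 1 and 1 of 16). Under scaling on ribosomal protein genes the medians of glycolysis (-0.10, 0 and 0 of 17), fatty acid and lipid genes (-0.10, 0 and 0 of 22), skeletal muscle markers (-0.17, 0 and 1 of 24) and mitochondrially encoded and nuclear-retained transcripts (-0.07, 0 and 0 of 14) changed sign, to 0.07, 0.08, 0.00 and 0.10. The contractile list was at an adjusted p of 0.369, and at 0.00343 without sham replicate 2 (range over the alternatives 0.00343 to 0.957). Of 24 macrophage markers Fcer1g, Ccr2, Tyrobp and Lyz2 rose, 5 adjusted over the list alone (median 0.37), Fcer1g by 2.43 ± 0.31, and the list was at 0.000146 without inhibitor-treated replicate 1 and 0.0346 without sham replicate 2 (range 0.000146 to 0.957). The calls for Tyrobp and Lyz2 were lost in 1 and 2 of 6 fits that left out 1 library. Of 30 FAK, integrin and focal adhesion genes 6 rose in both counts (0.04), Itga4 by 1.49 ± 0.15 and Lims1 by 0.42 ± 0.06. Among the 6, Vcl and Itga2 lost their calls in 3 and 2 of 6 fits that left out 1 library. The camera adjusted p of this list was 0.0346 without sham replicate 2 (range 0.0346 to 0.945). Among 26 modulated smooth muscle genes Thbs1 and Cd44 rose by 1.76 ± 0.25 and 1.09 ± 0.15, and Ly6a and Mgp were among the 3 that fell, with 4 and 4 adjusted over the list alone. The median of that list was 0.015, or -0.03 with quantile normalisation, and its test pointed downward.

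Among 24 inflammatory genes Il1b rose by 4.73 ± 0.55, Selp (P-selectin) by 0.76 ± 0.12, and Il33 fell, a call lost in 3 of 6 fits that left out 1 library, with 3 and 1 adjusted over the list alone (median 0.13). Rsad2 alone of 22 interferon genes rose, by 5.32 ± 0.40, 2 adjusted over the list alone (0.11). Mmp8, Mmp12 and Plaur rose and Mmp23 fell among 28 proteases and inhibitors, 6 and 1 adjusted over the list alone (0.14), but each of these calls was lost in at least 1 fit that left out a library. Other matrix genes gave Thbs1 higher and Fbln1 lower of 30 (-0.11, or 0.06 relative to ribosomal protein genes, then 1 and 2), and Runx1 rose by 1.77 ± 0.18 among 15 chondro-osteogenic genes (0.03, then 1 and 1). Gadd45a rose by 2.39 ± 0.20, with Tet3, among 17 DNA methylation genes (0.12, then 3 and 0). The remaining calls were Mta3 up of 14 NuRD genes (-0.03, or 0.14 relative to ribosomal protein genes, then 1 and 3), Tgfbi and Bmp4 down of 24 TGF-beta and BMP genes (0.00, or -0.01 with quantile normalisation, then 0 and 2), and Dusp1 down of 18 immediate early genes (0.06, then 0 and 1), whose test pointed downward. Tet3, Mta3, Tgfbi, Bmp4 and Dusp1 each lost the call in at least 3 of 6 fits that left out 1 library. Lists that passed when 1 library was left out included other matrix genes (0.00119 without sham replicate 3, range to 0.957), adipocyte markers (0.0021 without sham replicate 2, range to 0.957), endothelial markers (0.00373 without sham replicate 3, range to 0.957) and skeletal muscle markers (0.00458 without inhibitor-treated replicate 2, range to 0.957). Interferon response genes (0.0319) and fatty acid and lipid genes (0.0467) also passed without sham replicate 2, with ranges to 0.957. Mitochondrially encoded and nuclear-retained transcripts passed without sham replicate 1 (0.021, range to 0.957).

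The injury changes were set against the inhibitor changes, to describe how far genes changed by injury moved the other way in the treated group. Treatment and library preparation cannot be told apart in that group. Of 6068 genes called in injured against sham and measured in both comparisons, 97.2% had the opposite sign in inhibitor-treated against injured arteries. Among them 2523 rose with injury and fell with the inhibitor, including Mmp12, and 2124 fell and then rose, including Acta2, Myh11, Dsp and Sost. A further 59 rose in both and 0 fell in both, or 1 fell in both at an unadjusted limma p under 0.05.

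**Figure D4:**
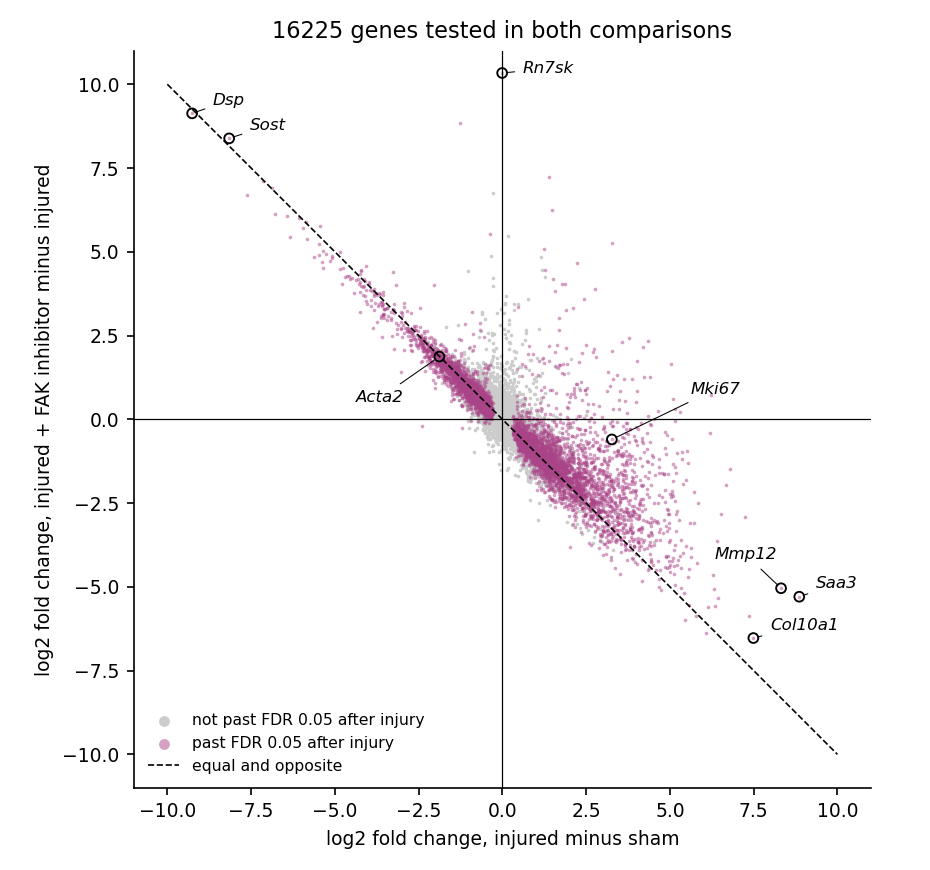
Log2 fold change of 16225 genes in injured against sham (horizontal) and inhibitor-treated against injured arteries (vertical), with a dashed line of equal and opposite change and 8 genes circled. Most genes lie along the dashed line, and Rn7sk lies far above it.

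Both comparisons use the same injured libraries, so opposite signs also arise by chance. In 100 simulated draws with no inhibitor effect the share was 56.3% ± 0.519 (SD), and in draws with the third group at the sham level it was 99.8%. Independent lists of these sizes would share 642 and 473 genes in the 2 directions. The draws held the 15575 genes present in all 3 tables, where the observed share was 97.0%, and about 7229 injury genes in each draw against 5659 observed. On these genes the covariance of the log2 fold changes was -0.920, against -0.0462 simulated with no effect, and the correlation was -0.826, across genes that are not independent replicates. The draws with no effect shared the injured libraries as the data do, so sharing as simulated gave 56.3% and not the observed 97.0%. This rests on the simulation, because the shared libraries were too few to split.

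Of 5666 injury genes measured against sham in the inhibitor-treated arteries, 457 (8.07%) were called there in the same direction as with injury, among them Mki67, Il1b, Thbs1, S100a8 and Runx1. Neutrophil, lymphocyte and platelet transcripts, S100a8 among them, were higher in all 3 inhibitor-treated libraries than in the sham libraries, and 28 of the 457 are members of blood cell lists. The share was 7.24% without blood, liver, skeletal muscle, small RNA, histone and immunoglobulin genes. This removal takes out only the members of the hand-made lists and those RNA classes. Other transcripts of blood cells stay in, so how much of the share they make up was not tested. The share was 5.13% without sham replicate 1, 5.33% without inhibitor-treated replicate 1 and 4.59% without inhibitor-treated replicate 2. Over all fits that left out 1 library it reached 8.94%, and it was 12.6% at an absolute log2 fold change of at least 1. The median ratio of the inhibitor-treated to the injury change was 0.114. It was 0.0259 in draws with the inhibitor-treated group at the sham level and 0.974 at the injured level.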

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

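The tests with edgeR, without 3 libraries that stood apart (injured replicate 2, sham replicate 3, inhibitor-treated replicate 3) and without blood, liver, muscle, small RNA, histone and immunoglobulin genes, and the medians of all lists under other scalings, were chosen after the results were seen, although the scaling test of the contractile list was set before its own result. Of 409 results for named genes, 94 lost and 42 gained a call in at least 1 alternative, and 0 changed sign while called. Of 90 list tests, 43 lost and 24 gained a call, fry included. The counts of genes stayed within 1.5 times with DESeq2, edgeR, quantile normalisation, other pseudocounts, no filter on low values and all 9 libraries in 1 fit. For injured against sham (6076) the count was 9621 with sample weights, 3432 at an absolute log2 fold change of at least 1 and 3835 at an adjusted p under 0.01. For inhibitor-treated against injured (6099) these were 10651, 3250 and 3497, with 3295 without those 3 libraries. For inhibitor-treated against sham (983) the count was 617 and 414 under the latter 2 thresholds and 551 at a mean of at least 100. The stricter thresholds and the higher mean lower counts by construction, and the cause of the other changes was not tested. With a replicate block the counts were 5762, 5747 and 877, and the correlations between libraries of the same number lay between -0.076 and 0.192, so the numbers were not treated as pairs.

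With an estimated correlation 0 lists passed in injured against sham, 0 in inhibitor-treated against injured and 0 in inhibitor-treated against sham, where fry, a test against no change, passed 3. The median of the oxidative phosphorylation list in inhibitor-treated against sham was 0.019 with scaling on ribosomal protein genes, which moves all genes upward by construction. Genes up after injury and lower with the inhibitor numbered 1576, and those down and then higher 1114, without those 3 libraries, and the latter numbered 942 at an absolute log2 fold change of at least 1. The percent of injury genes called in the same direction against sham was 12.641 at that threshold. Leaving out 1 library at a time gave 4356 to 7277, 4080 to 7926 and 518 to 854 genes in the 3 comparisons, and 16 to 20, 16 to 22 and 7 to 15 lists. Where this leaves 2 libraries in a group, the spread is pooled over both groups. In inhibitor-treated against sham the count was 518 without sham replicate 1, 596 without sham replicate 2, 598 without inhibitor-treated replicate 1 and 533 without inhibitor-treated replicate 2, and the 15 lists came without sham replicate 2. The opposite-direction counts ranged from 1911 to 3118 and 1541 to 2841, with 96.9% to 97.4% of opposite sign. The percent called in the same direction against sham ranged from 4.5907 (without inhibitor-treated replicate 2) to 8.9433, with 5.13 without sham replicate 1 and 5.33 without inhibitor-treated replicate 1. Genes with few reads are absent from the deposited tables, so depth limits what can be said of them.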

Other observations

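Of the tests below, those of bone marrow, scaling, imprinted genes and library splits were set before their results were seen, and those of liver RNA, a response to the inhibitor, retained blood, library preparation, the smooth muscle share and collection time were chosen after. H19, an imprinted noncoding RNA, lay at 181, 148 and 290 in sham, 5561, 15380 and 4313 in injured, and 72.1, 604 and 290 in inhibitor-treated libraries. Of 19 imprinted genes 13 rose and 3 fell with injury, 4 rose and 11 fell with the inhibitor, and 1 rose against sham. Grb10, an adaptor of growth factor receptors, was at 1729 ± 60.9 in sham, 4068 ± 652 in injured and 1668 ± 202 in inhibitor-treated libraries. Of the 18 measured beside H19, 12 (66.7%) rose with injury, against 20.6% of all genes tested. The list was written after the data were examined, and 2 of its members are also in other lists, so the share is not independent evidence. A joint rise of imprinted genes is a hypothesis that may describe the H19 change.

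Of 17 circadian clock genes 3 rose and 9 fell with injury, 6 rose and 1 fell with the inhibitor, and 0 were called against sham with limma. Dbp, a clock output factor, was at 7110 ± 1409 in sham, 2602 ± 148 in injured and 5191 ± 1588 in inhibitor-treated libraries. Of 21 histone genes 12 were higher in the inhibitor-treated libraries in each of their 2 comparisons. A preparation that kept RNAs without a poly(A) tail cannot be told apart from the treatment here, as described below. T and NK cell markers rose with injury in 13 of 13, and in 13 of 14 in inhibitor-treated against sham. Platelet genes rose in 12 of 12 with the inhibitor against injured and against sham, B cell genes in 3 and 6 of 13, and with injury 4 of 6 and 5 of 7 rose. Immunoglobulin genes rose in 22 of 29 with injury, 13 of 36 fell and 1 rose with the inhibitor, and 9 of 15 rose in inhibitor-treated against sham. Of 4 Y-linked genes 3 were higher with the inhibitor against injured and 1 against sham. Xist, of the inactive X, was at 5749 ± 1466 in sham, 7030 ± 4194 in injured and 3476 ± 603 in inhibitor-treated libraries, and the mean log2 level of the Y-linked list was 8.65 ± 0.438, 8.78 ± 0.246 and 9.52 ± 0.16. Both were present in each library, Xist at 2654 to 11014 and the Y-linked Ddx3y at 849 to 1814, which argues against libraries from a single sex. Whether the mix of sexes differs by group stays open, and the Y-linked calls are not read as effects of the inhibitor.

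Hepatocyte transcripts were high in inhibitor-treated replicate 3 alone, with Alb at 16023 there and 14.0 to 70.6 in the others, and Apob at 7113. The list's median in inhibitor-treated replicates 1 and 2 was 0.509 log2 above sham. The list was written for a pattern high in replicate 3 alone. This value therefore cannot test a response of the artery to the inhibitor. RNA from liver in replicate 3 and such a response in that library stay open. The list was written after this library was seen to be high, so the 23 of 24 hepatocyte genes (95.8%) that lay at least 4 log2 above both other inhibitor-treated libraries describe the pattern and do not test its origin. Of these 24 genes 1 lay at 100 or more in sham.

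Blood cell transcripts were high in all 3 inhibitor-treated libraries, with Alas2 at 30976, 72797 and 43268 against 64.5 to 313 in the others, although the labels describe a lumen rinse. Whole blood with its globin transcripts is argued against, because globins differed from sham by -0.373 ± 0.308 (SE) while other erythroid genes differed by 6.63 ± 0.423. Blood from which globin RNA was removed during preparation is not covered by this test and stays open. Bone marrow is argued against, because granulocyte precursor genes differed by 0.217 ± 0.602 and mature neutrophil genes by 6.00 ± 0.237. A preparation that kept RNAs without a poly(A) tail cannot be told apart from the treatment. In the inhibitor-treated libraries 7 such RNAs and 11 of 21 histone genes (64.3% together) lay above every other library. Of all 16750 genes 888 (5.3%) did so. However, some of the 7 RNAs were already known as the largest rises when they were picked. Removal of globin RNA in such a preparation could leave blood with few globin reads. Another preparation judged on small RNA genes as a class cannot be told apart from the treatment, with a class median of 0.388 against sham and 0.475 against injured, since each group may have been prepared together.

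Contractile genes were lower in injured than in sham. Scaling is argued against, since the median nearest 0 among 4 scalings was -1.33. A lower smooth muscle share with all other cell types raised alike is argued against, because the macrophage, endothelial, fibroblast and adipocyte medians lay up to 3.137 apart. A lower smooth muscle share with other cell types raised unequally, such as a rise of macrophages, was not tested and stays open. A shift in collection time cannot be told apart, as Per2 in inhibitor-treated arteries differed from sham by -0.547 ± 0.382 and Dbp by -0.48 ± 0.318, within the spread. Injury itself, which the design names, stays among the open explanations and could act together with these.

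Groups of 3 and 3 libraries make 10 splits, too few for a share under 0.05. Of these, 1 split gave as many genes as the real one in each comparison, namely the real one, with 6076, 6099 and 983 genes and 0 as the highest of the others in each.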
